A study of Bacillus cereus ATCC 14579 with 12 samples.

How the data were processed

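RNA of Bacillus cereus ATCC 14579, a spore-forming Gram-positive food-borne pathogen, was compared between biofilm cells grown for 12 h or 24 h and planktonic cells taken in mid-logarithmic or stationary phase. Per the labels' protocols, complementary DNA was labelled with Cy3 or Cy5 and each array held 2 conditions. The series held 12 Agilent 2-colour arrays of 60-base probes on 6 slides. Each array carried 10262 gene probes for 5131 genes, 2 probes per gene, and 544 control spots. Genes are named by the locus tags in the probe names. No annotation, coordinates or genome came with the arrays, so locus tags were not paired with gene names by the files. The names sipW, tasA, calY, sinR, sinI, spo0A, plcR and sigB were tied to locus tags before the data were examined, from knowledge of this strain, and were not checked against an annotation.

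Per the file headers, the authors extracted spot intensity with Agilent Feature Extraction 9.5.1.1, which gave the mean spot intensity and the median local background intensity of both dyes with no normalization. Per the file headers, the same program also gave processed intensity values, which were background-subtracted, spatially detrended and dye-normalized by lowess, with outlier marks for uneven spots. The file's own log ratio, per the file headers a log10 of processed Cy5 over processed Cy3 signal, was used for a check of the unit only. The deposited series value table held, for each array, a log2 ratio of processed Cy5 over processed Cy3 signal. This was tested on the values, where the correlation was 1 and 100% of the gene probes lay within 0.01 on every array, with no centring. The column medians of that table were 0.158 and 0.08 for the arrays with both biofilms, -0.0593 and 0.0771 for 12 h biofilm with stationary cells, 0.0288, -0.165 and 0.223 for 12 h biofilm with mid-log cells, 0.218 for 24 h biofilm with mid-log cells, -0.0664 and 0.00963 for mid-log with stationary cells, and 0.019 and 0.0783 for 24 h biofilm with stationary cells. Its scale and centring are therefore known, and its direction is that of the dyes.

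The labels name the condition in each channel, and the array titles name the conditions in an order. On 11 of the arrays the first-named condition of the title carries the Cy3 label. The planned analysis used the channel labels. It was first run in full that way. In that run the fits with 1 value per RNA sample called 0 genes for stationary against mid-log and for 24 h biofilm against mid-log cells, and the array-level fit gave a lower tasA, eps2 cluster and purine cluster in biofilms, and higher ribosomal-protein and lower sporulation genes in stationary cells. Only after those results were seen were the signal profiles of single channels compared between arrays. Processed signals of each dye were averaged per gene, quantile-normalized and centred per gene. Profiles that share a condition by the channel labels had a median correlation across genes of -0.39, and profiles that share a condition by title order, with the first-named condition in Cy5, had one of 0.96. The title order was then taken as the direction of every array, so the direction reported here is likely, not settled, and it was chosen after the first results were known. For the 8 arrays fitted together this turns every sign and leaves each size, count and p-value of the array-level fits as it was. Values per RNA sample do change: biofilm against planktonic samples gave 281 genes by the channel labels, where 2 of the 35 splits of the samples gave as many and 1 other split gave 294, and 717 by title order, where the highest other split gave 5. The expected directions first written down for ribosomal-protein and sporulation genes were replaced by the profile comparison after their values were seen, and the signs in the tests of the left-out arrays were restated then too. The peptide patterns for ribosomal proteins were chosen after the values of those genes were seen, and the patterns for sporulation proteins were extended once.

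The fit used the 8 arrays whose labels conflict with neither each other nor the design text. Left out were 2 arrays that compare both biofilms, because their dyes are labelled alike although the design text names a dye swap, and 2 arrays whose channel labels are equal (12 h biofilm sample 1 with mid-log sample 2). By title order the dyes of the arrays that compare both biofilms are swapped. In the fit, mid-log cells were on 4 arrays, 12 h biofilm on 3, 24 h biofilm on 3 and stationary cells on 6, with 2 RNA samples per condition. Background was corrected with normexp (offset 50), and log ratios were normalized within each array by loess with limma 3.58.1 in R 4.3.3. Control spots had weight 0, and outlier-marked spots were set to missing (1366 values on the 8 arrays). Probes had to be well above background in either channel on at least 2 arrays, a minimum set after the files were seen, which kept 10196 probes of 5123 genes. The log2 ratios of both probes were averaged per gene. The probes of 1 gene were called in opposite directions for 392 genes in stationary against mid-log cells, 253 in 12 h biofilm against stationary cells, 184 in 24 h biofilm against stationary cells, 12 in 24 h biofilm against mid-log cells and 5 in 12 h biofilm against mid-log cells.

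A linear model with a dye term was fitted to each gene over the 8 arrays (lmFit and eBayes), which left at most 4 residual degrees of freedom with a prior of 2.72. The 6 contrasts between conditions were tested two-sided by limma's moderated test with Benjamini-Hochberg adjustment at 0.05. Errors given as ± are the model's standard errors over the 8 arrays. By title order Cy5 held sample 1 and Cy3 sample 2 on 7 of the 8 arrays, so the dye term and the sample number are nearly confounded, and a difference between the RNA samples of 1 condition includes the dyes. RNA samples recur on several arrays, so arrays are not fully independent and the p-values may be too small. A gene counted as changed in 1 direction in both biofilms against both planktonic conditions when its 4 contrasts had the same sign and the largest of the 4 p-values passed the adjustment over all genes. Values per RNA sample were means of the separate channels after loess and Aquantile normalization, and were used for a comparison of 4 biofilm with 4 planktonic RNA samples.

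Gene lists were fixed by locus tag before the data were examined, and 7 could be tested: flagella and chemotaxis, the TasA fibre and SinI-SinR region, the exopolysaccharide clusters eps1 and eps2, toxins and PlcR-regulated virulence factors, purine biosynthesis, and the sigma B general stress genes. A further 21 lists, and the genes codY, comK and abrB, were defined by gene product or symbol and were not tested for want of an annotation. Lists were tested with camera (preset correlation 0.01) in the 6 contrasts, 42 tests adjusted together, then with an estimated correlation and with fry, which tests whether a list's genes move on balance one way. camera and fry used the members with a value on all 8 arrays: 36 of 44 flagella, 13 of 17 eps1 and 9 of 14 toxin genes, and all measured members of the other lists. List medians and counts of members used every measured member. The genes named were fixed by rule: the 8 names above, the 3 members with the largest change of each called list (up to 5 lists by smallest p), and the genes with the largest changes. As that last part required an annotated function, at most 2 unnamed locus tags are given in each direction of a comparison. List members named beyond the rule, where 1 member went against its list or a list was not called, were chosen after their values were seen.

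On simulated data made from the 12 h biofilm against mid-log comparison with 200 of 5123 genes changed, 23% of genes changed by 1 on the log2 scale and 97% of those changed by 3 were recovered, and 6.25% of calls were false. With 50% of the variance shared by arrays of 1 RNA sample, 57% and 98% were recovered and the false share was 20.1%. Alternatives tried were other background corrections and normalizations, the filter on dim probes, the processed signals and the series value table, no dye term, a sample-number term, 1 value per RNA sample, the arrays left out, the brighter probe of each gene, the slide as a random block, each array left out and other thresholds. Added after the data were seen were outlier-marked spots kept on the array with the most of them, the pooled comparison without each RNA sample or by the channel labels, and other settings for the correlation of the direct arrays. Fitted as a fixed term, the slide left no residual degrees of freedom.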

Results

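The data were 12 Agilent arrays with 2 colours for Bacillus cereus ATCC 14579. By their labels, 3 compared 12 h biofilm with mid-log cells, 2 compared 12 h biofilm with stationary cells, 1 compared 24 h biofilm with mid-log cells, 2 compared 24 h biofilm with stationary cells, 2 compared mid-log with stationary cells and 2 compared both biofilms. The 8 arrays without a label conflict entered the fit, with 2 RNA samples for each of the 4 conditions. The median spot signal per array ran from 166.8 to 626.2 in Cy3 and from 71.35 to 268.9 in Cy5, over background medians of 43 to 50. Between 90% and 98.5% of gene probes were well above background in Cy3, and between 56.6% and 91.6% in Cy5. Saturated spots hold a signal down: on the 8 arrays all 8 mid-log spots of BC1658 were saturated, 9 of 12 stationary spots of BC0390, 1 of 8 mid-log spots of BC5101, and in 24 h biofilm 3 of 6 spots of BC1016, 2 of 6 of tasA (BC1279) and of BC3555 and 1 of 6 of BC0252. Changes of these genes between the saturated condition and a condition with lower signal can be underestimated, and falls from 12 h to 24 h biofilm can be overestimated. Replicate arrays with swapped dyes correlated across genes, which are not independent replicates, at 0.9 for 12 h biofilm with stationary cells, 0.89 for 24 h biofilm with stationary cells and 0.97 for mid-log with stationary cells.

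The direction of every ratio below follows the order of conditions in the array titles, and it is the opposite of the direction given by the channel labels. Same-dye signal profiles of channels that share a condition by title order correlated at a median of 0.96 across genes over 11 pairs of channels (range 0.91 to 0.97). The 11 pairs that share a condition by channel label had a median of -0.39 (range -0.71 to 0.57), close to the median of -0.44 between different conditions. The highest correlation between different conditions by title order was 0.57. These values argue against the channel labels as written, under which channels of 1 condition would share a profile. As title order was found from these data, the direction is called likely. If the channel labels hold, higher reads lower and lower reads higher in each comparison, while each size, count and p-value of the array-level fit stays as printed.

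**Figure D1:**
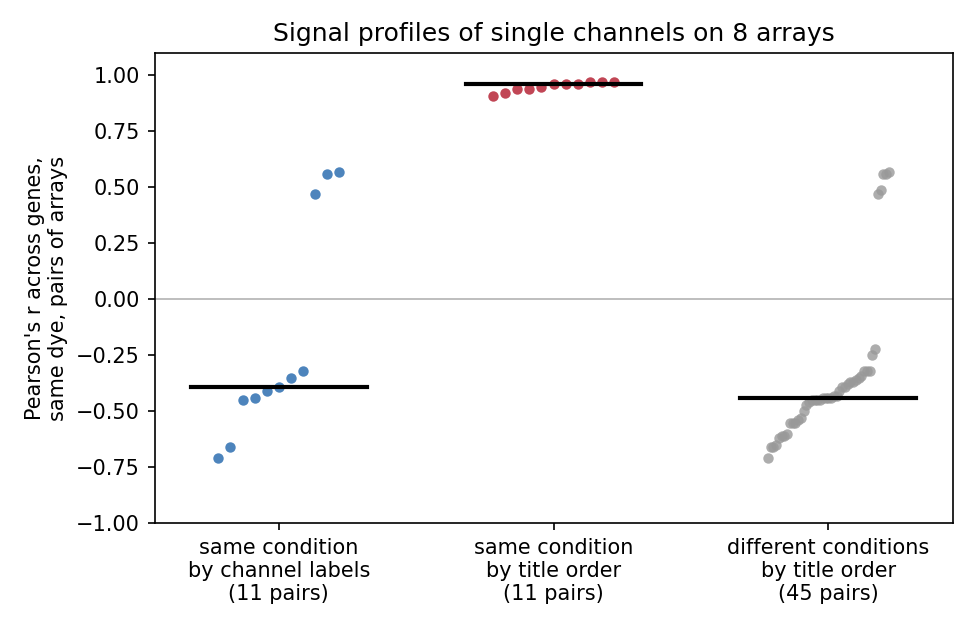
Pearson's correlation across genes between single-channel signal profiles of the same dye on pairs of the 8 arrays (y axis, no unit), for pairs that share a condition by channel label, pairs that share one by title order, and pairs of different conditions by title order. Points are pairs of channels and bars are medians, at -0.39, 0.96 and -0.44.

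Biofilm formed in 12 h was compared with exponentially growing planktonic cells to find genes that differ between biofilm and planktonic growth. The TasA fibre genes, which encode the protein fibres of the biofilm matrix in Bacillus, were far higher in the biofilm. The locus taken as tasA, BC1279, was 195-fold higher (log2 7.60 ± 0.78, adjusted p = 0.00145), its paralogue calY, BC1281, was 89.6-fold higher (6.49 ± 0.67, adjusted p = 0.00148), and sipW, BC1278, which encodes the signal peptidase of TasA, was 71.7-fold higher (6.16 ± 0.71, adjusted p = 0.00181). All 6 members of the TasA and SinI-SinR region rose, with a median log2 change of 4.27, and the matrix regulators sinR (1.79 ± 0.34) and sinI (1.67 ± 0.38) rose less. In the eps2 exopolysaccharide cluster 8 of 9 genes rose (median 4.97), among them BC1583 by 91.3-fold (6.51 ± 0.57, adjusted p = 0.00103), BC1585 by 71.7-fold and BC1586 by 54.4-fold. Of the 10 purine biosynthesis genes 9 rose (median 3.83), led by BC0332 at 44.9-fold (5.49 ± 0.38, adjusted p = 0.000679), BC0331 at 27.1-fold and BC0330 at 18.9-fold. Flagellar and chemotaxis genes moved the other way: 43 of 44 fell (median -2.42), with BC1658 17.2-fold lower (-4.11 ± 0.38, adjusted p = 0.00116), BC1644 16.1-fold lower and BC1638 15.5-fold lower, and 1 member, BC1655, rose by 3.07 ± 0.48. Of 14 toxin and PlcR-regulated genes 10 fell (median -1.70), including BC0670 at 25.2-fold (-4.66 ± 0.21, adjusted p = 0.000525), BC1110 at 14.3-fold, BC1811 at 4.99-fold and plcR itself, BC5350, the regulator of these virulence factors, at 4.90-fold (-2.29 ± 0.52). In the eps1 exopolysaccharide cluster 9 of 17 genes fell and 8 did not pass the test (median -0.82). The master regulator of sporulation and matrix genes, spo0A (BC4170), was 4.98-fold higher (2.32 ± 0.38, adjusted p = 0.00437), while sigB (BC1004) stood at -0.11 ± 0.36 (adjusted p = 0.827) and 6 of 18 general stress genes rose.

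In all, 2040 of 5123 genes changed between 12 h biofilm and mid-log cells, 1085 higher and 955 lower in the biofilm, and 1657 of them by at least 2-fold. The unnamed loci with the largest rises were BC1016 (9.45 ± 0.62) and BC3555 (8.78 ± 0.78), and those with the largest falls were BC5438 (-5.34 ± 0.58) and BC5380 (-5.27 ± 0.62). By camera the flagella list (adjusted p = 2.49e-14), the eps2 cluster (4.67e-05), purine biosynthesis (4.78e-05), the toxin list (0.000422), the TasA region (0.000933) and the eps1 cluster (0.0066) passed. With an estimated correlation none did: adjusted p = 0.441 with an estimated correlation for the first 5 of these lists and adjusted p = 0.473 with an estimated correlation for eps1, which also missed the threshold with the brightest probe of each gene (-0.69, adjusted p = 0.0602). Adjusted over the list alone, the counts of members higher and lower were the same in each of these lists. With the slide as a random block 2027 genes changed. Without the first array of 12 h biofilm with stationary cells 1137 genes changed, and without the only fitted array of 12 h biofilm with mid-log cells 1086 did; with the channel labels as written the 1085 would be lower and the 955 higher. The balance depended on the processing: 764 were higher and 349 lower over probes above background in both channels on every array, 1268 higher and 1782 lower with median centring, and 1389 higher and 1819 lower with processed signals.

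**Figure D2:**
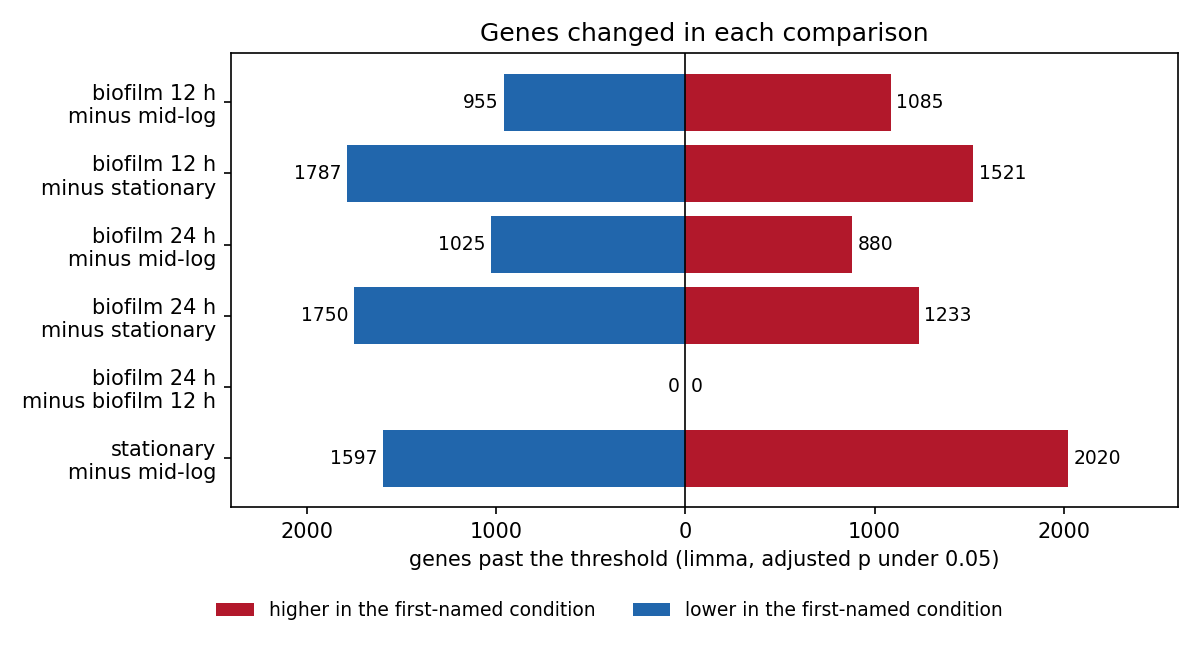
Number of genes past the threshold (x axis, genes) that were higher (right) or lower (left) in the first-named condition of each of the 6 comparisons (y axis), by limma at an adjusted p under 0.05. Stationary against mid-log cells had 2020 higher and 1597 lower, and 24 h against 12 h biofilm had 0 of either.

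Biofilm of 24 h showed the same groups against mid-log cells, although its 2 RNA samples differed for some of the genes. Their log2 signals were 9.14 and 12.21 for sipW and 11.86 and 14.66 for tasA, and the errors below are over arrays. The tasA locus, BC1279, was 89-fold higher (6.48 ± 0.78, adjusted p = 0.00255), calY, BC1281, was 83.4-fold higher (6.38 ± 0.67, adjusted p = 0.00185), sipW, BC1278, was 26.8-fold higher (4.75 ± 0.71) and 5 of 6 members of the region rose (median 3.52; 6 adjusted over the list alone). In the eps2 cluster 8 of 9 genes rose (median 4), with BC1583 44.5-fold higher (5.48 ± 0.57, adjusted p = 0.00172), BC1585 31.7-fold and BC1586 27.5-fold, and 9 of 10 purine genes rose (median 2.64), with BC0328 10.3-fold higher, BC0332 8.92-fold and BC0327 8.56-fold. Flagellar genes fell in 42 of 44 cases (median -2.47), BC1658 by 47-fold (-5.55 ± 0.38, adjusted p = 0.000933), BC1644 by 28-fold and BC1638 by 27.6-fold, while BC1655 again rose (1.89 ± 0.48). In the eps1 cluster 15 of 17 genes fell (median -1.70; 16 adjusted over the list alone), with BC5278 9.90-fold lower, BC5264 5.49-fold lower and BC5277 5.41-fold lower. Of the toxin genes 9 of 14 fell (median -1.40), plcR (BC5350) among them at 6.13-fold lower (-2.62 ± 0.52, adjusted p = 0.0096). The locus spo0A, BC4170, was 3.72-fold higher (1.89 ± 0.38), sinR was 4.25-fold and sinI 4.91-fold higher, and sigB, BC1004, stood at -0.10 ± 0.36 (adjusted p = 0.849).

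Between 24 h biofilm and mid-log cells 1905 genes changed, 880 higher and 1025 lower in the biofilm. The unnamed loci that changed most were BC1016 (8.57 ± 0.62) and BC0252 (7.79 ± 0.40) upward and BC5380 (-5.81 ± 0.62) and BC5438 (-5.71 ± 0.58) downward. In camera the flagella list (adjusted p = 2.49e-14), eps2 (4.67e-05), eps1 (4.78e-05), purine biosynthesis (4.78e-05), the TasA region (0.000793) and the toxin list (0.00428) passed, and each had an adjusted p = 0.441 with an estimated correlation. With the slide as a random block the count was 1887. It fell to 789 without the only array that compares 24 h biofilm with mid-log cells directly, on which 1122 probes carried outlier marks, and to 1081 without the first array of 24 h biofilm with stationary cells, where the toxin list also no longer passed (adjusted p = 0.0553); with the channel labels as written the 880 would be lower and the 1025 higher. Over probes above background in both channels on every array 768 were higher and 387 lower, with the brightest probe of each gene 890 and 729, and with processed signals 1304 and 1679.

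**Figure D3:**
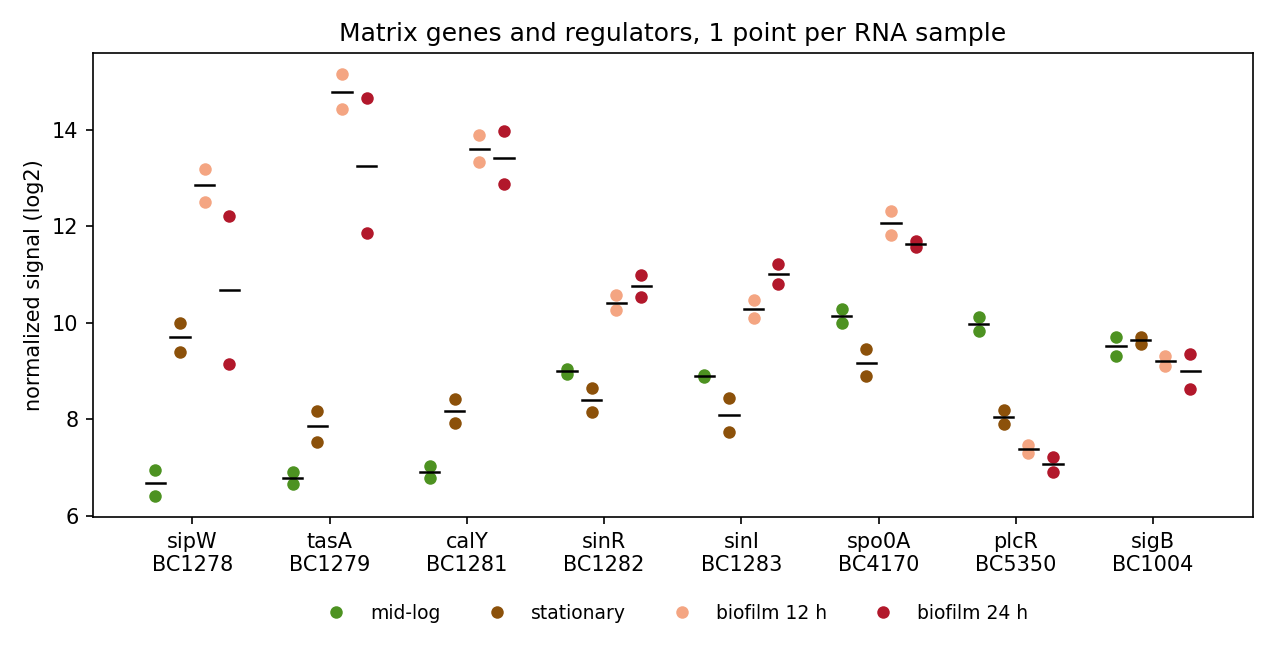
Normalized signal (y axis, log2) of 8 genes fixed before the data were examined (x axis, with locus tags), 1 point per RNA sample and a bar at the mean of the 2 RNA samples of each condition. For tasA the biofilm samples lie between 11.86 and 15.16 and the planktonic samples between 6.66 and 8.17.

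Biofilm was also compared with stationary cells, the planktonic cells that no longer grow. After 12 h tasA, BC1279, was 107-fold higher than in stationary cells (6.75 ± 0.66, adjusted p = 0.000374), calY, BC1281, 41.7-fold higher (5.38 ± 0.57, adjusted p = 0.00047) and sipW, BC1278, 7.35-fold higher (2.88 ± 0.60), and all 6 genes of the region rose (median 2.59). In the eps2 cluster 8 of 9 genes rose (median 4.06), led by BC1585 at 35.9-fold (5.17 ± 0.54, adjusted p = 0.000447), BC1583 at 27.3-fold and BC1584 at 20.5-fold, and the last gene of the cluster, BC1591, fell by 4.15 on the log2 scale. All 10 purine genes rose (median 2.67), with BC0331 10.1-fold higher, BC0327 9.37-fold and BC0329 8.22-fold. The locus spo0A, BC4170, was 8.14-fold higher (3.03 ± 0.32, adjusted p = 0.000472). Flagellar genes were not called as a list (median -0.43, adjusted p = 0.247): 14 fell, 2 rose and 28 did not pass. That list did pass with 1 value per RNA sample, and its median ran from -0.73 to -0.25 without 1 array at a time. Of 17 eps1 genes 8 rose and 1 fell (median 0.53, adjusted p = 0.247), and of 14 toxin genes 6 rose and 4 fell (median 0.26, adjusted p = 0.505). The general stress genes were not called (median 0.24, adjusted p = 0.26), and sigB, BC1004, stood at -0.50 ± 0.30 (adjusted p = 0.182).

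Between 12 h biofilm and stationary cells 3308 genes changed, 1521 higher and 1787 lower in the biofilm. The largest unnamed changes were BC3555 (7.81 ± 0.66) and BC1523 (6.78 ± 0.58) upward and BC4026 (-8.59 ± 0.69) and BC4764 (-8.46 ± 0.61) downward. In camera purine biosynthesis (adjusted p = 0.00012) and the TasA region (adjusted p = 0.00129) passed, each with adjusted p = 0.441 with an estimated correlation, and eps2 (adjusted p = 0.00146) passed with adjusted p = 0.473 with an estimated correlation. The median changes within the slide that holds both direct arrays were 2.41 for the TasA region, 3.56 for eps2 and 2.39 for purine biosynthesis. With the slide as a random block 3286 genes changed, and with the channel labels as written the 1521 would be lower and the 1787 higher. Over probes above background in both channels on every array, 2203 of 3132 genes changed, 700 higher and 1503 lower.

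After 24 h most matrix genes were still above stationary cells. By RNA sample the log2 signal of sipW at 24 h was 9.14 in sample 1, below both stationary samples (9.99 and 9.4), and 12.21 in sample 2, above both. The tasA locus, BC1279, was 49.1-fold higher (5.62 ± 0.66, adjusted p = 0.000843), calY, BC1281, 38.8-fold higher (5.28 ± 0.57, adjusted p = 0.000589) and sinI, BC1283, 7.58-fold higher (2.92 ± 0.32, adjusted p = 0.00064), while sipW, BC1278, stood at 1.46 ± 0.60 and did not pass (adjusted p = 0.0762). Of the region 5 of 6 genes rose (median 2.67; 6 adjusted over the list alone). In the eps2 cluster 8 of 9 rose (median 3.18), with BC1585 15.9-fold, BC1583 13.3-fold and BC1584 10.8-fold higher, and BC1591 fell by 4.09 on the log2 scale. Of the 10 purine genes 8 rose (median 2.09), with BC0325 8.01-fold, BC0327 6.56-fold and BC0324 6.29-fold higher. The locus spo0A, BC4170, was 6.08-fold higher (2.60 ± 0.32). Of the toxin genes 7 rose and 2 fell (median 0.39, adjusted p = 0.241). The flagella list (median -0.63, adjusted p = 0.104), eps1 (median -0.21, adjusted p = 0.816) and the general stress list (median -0.13, adjusted p = 0.754) were not called, and for general stress camera ranked the list upward although its median and mean (-0.17) were below 0. The flagella list did pass with 1 value per RNA sample, processed signals or median centring. Its median ran from -0.98 to -0.37 without 1 array at a time.

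Between 24 h biofilm and stationary cells 2983 genes changed, 1233 higher and 1750 lower in the biofilm. The largest unnamed changes were BC3555 upward (6.37 ± 0.66) and BC3515 (-9.51 ± 0.51) and BC0391 (-9.27 ± 0.55) downward. The TasA region (adjusted p = 0.000933; adjusted p = 0.441 with an estimated correlation), purine biosynthesis (adjusted p = 0.000543; adjusted p = 0.472 with an estimated correlation) and eps2 (adjusted p = 0.00129; adjusted p = 0.473 with an estimated correlation) passed in camera. Within the slide of the direct arrays their medians were 2.58, 1.88 and 2.93. With the slide as a random block 2939 genes changed, and with the channel labels as written the 1233 would be lower and the 1750 higher. Without the first array of 24 h biofilm with stationary cells 1413 genes changed, and over probes above background in both channels on every array 518 were higher and 1532 lower. The balance depended on the processing: the median log2 change of all genes was -0.15 in the fit and -0.74 with that filter. It was -0.05 with median centring and -0.04 with processed signals.

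The title of the series sets biofilm against planktonic cells, and 96 genes changed in 1 direction in both biofilms against both planktonic conditions, 93 higher and 3 lower in biofilm. Regardless of the threshold, 2216 of 5123 genes had the same sign in all 4 contrasts, 1096 higher and 1120 lower. The excess of higher genes thus holds only among those past the threshold. The 93 held tasA (BC1279, smallest of the 4 log2 changes 5.62, adjusted p = 0.0133) and calY (BC1281, 5.28, adjusted p = 0.0109), 5 of the 9 eps2 genes (BC1583, BC1584, BC1585, BC1586 and BC1588, smallest changes 3.18 to 3.99) and 1 purine gene, BC0326 (2.02). The largest unnamed locus was BC3555 at 6.37. The 3 lower genes were BC1804 (smallest change in size 2.37, adjusted p = 0.0138), BC1376 (1.30) and BC5245 (1.09, adjusted p = 0.0437, named after its value was seen). No flagellar, toxin, eps1 or general stress gene of the lists was among the 96. The count rested on few arrays: it ran from 0 without either array of 24 h biofilm with stationary cells to 213 without the second array of 12 h biofilm with stationary cells, and was 1 without the first of these, 6 without the array of 24 h biofilm with mid-log cells, 22 without the array of 12 h biofilm with mid-log cells, and 46 and 164 without the first and the second array of mid-log with stationary cells. With processed signals and no loess it was 829 (513 higher), and with the channel labels as written the 93 would be lower and the 3 higher.

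With 1 value per RNA sample, the 4 biofilm samples differed from the 4 planktonic samples in 717 genes by limma (483 higher and 234 lower in biofilm). The count was 470 with the sample number as replicate block. It was 281 with the channel labels as written, and 361 without the second 12 h biofilm sample, 431 without the first, and 447 and 436 without the first and the second mid-log sample.

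**Figure D4:**
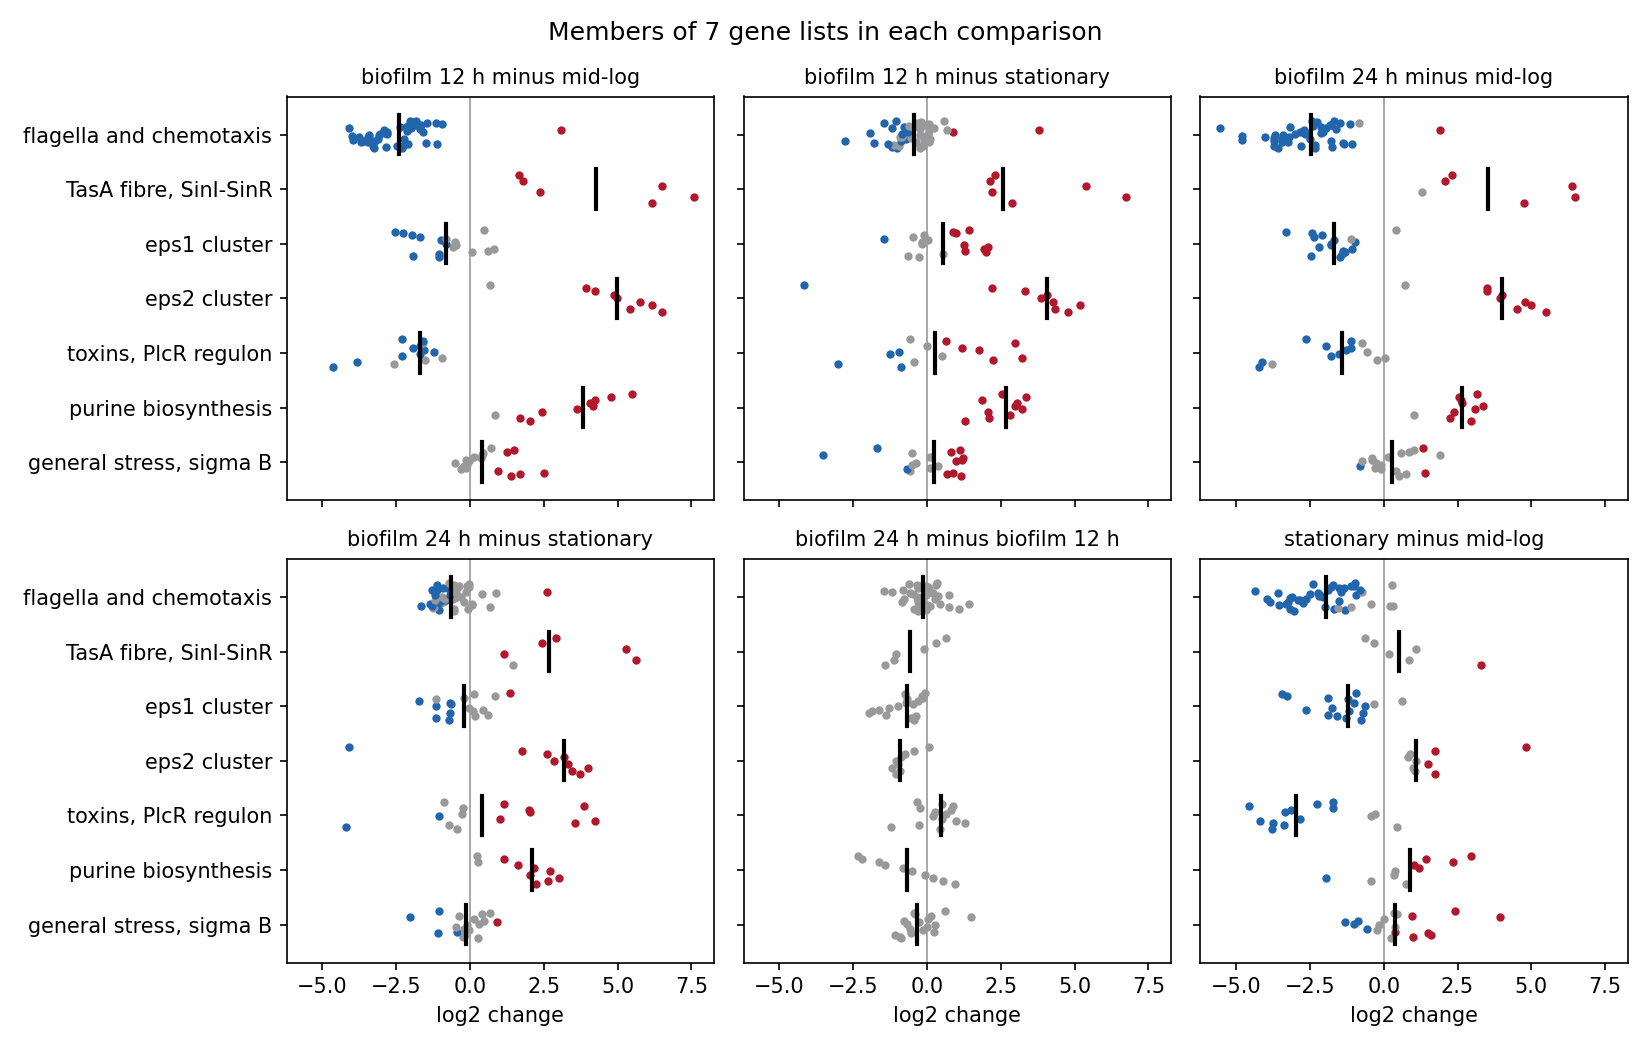
Log2 change (x axis) of each measured member of the 7 gene lists (y axis) in each of the 6 comparisons; red and blue points passed the threshold upward and downward, grey points did not, and black bars are list medians. The eps2 cluster has medians of 4.97 and 4 against mid-log cells and 4.06 and 3.18 against stationary cells.

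The step from 12 h to 24 h of biofilm growth gave far smaller differences. By limma 0 of 5123 genes passed, the smallest adjusted p was 0.0891, and 598 genes had an unadjusted p under 0.05. That count leaves out both direct arrays, and it rose when they were added by title order, as given below. The tasA locus, BC1279, stood at -1.13 ± 0.89 (adjusted p = 0.668), sipW, BC1278, at -1.42 ± 0.81 (adjusted p = 0.546) and spo0A, BC4170, at -0.42 ± 0.43 (adjusted p = 0.746). As a list, eps1 was lower at 24 h in camera (median -0.66, adjusted p = 0.000717), with 0 of 17 genes past the threshold over all genes and 6 lower when adjusted over the list alone. It had adjusted p = 0.441 with an estimated correlation and 0.124 with fry, missed the threshold with the brightest probe of each gene (-0.53, adjusted p = 0.0544) and turned to 0.03 with both direct arrays added against title order. Its median ran from -1.05 to -0.38 without 1 array, the lower without the second array of 24 h biofilm with stationary cells and the higher without the array of 24 h biofilm with mid-log cells. For 11 of its 17 genes both 24 h RNA samples lay below both 12 h samples, and for 0 they lay above. The toxin list was higher at 24 h (median 0.47, adjusted p = 0.0484; adjusted p = 0.473 with an estimated correlation and 0.42 with fry), with 0 of 14 genes past the threshold. By RNA sample both 24 h samples lay above both 12 h samples for 3 of the 14 and below them for 2, and for 5 the 24 h samples lay on opposite sides of the 12 h samples. The other lists did not pass: eps2 (median -0.92, adjusted p = 0.0696), purine biosynthesis (median -0.66, adjusted p = 0.0872), general stress (median -0.34, adjusted p = 0.182), the TasA region (median -0.58, adjusted p = 0.763) and flagella (median -0.14, adjusted p = 0.787). Of these, eps2 passed in several alternatives, among them processed signals (adjusted p = 0.0297), no dye term (0.0333), the brightest probe (0.0439), the stricter filter (0.0476), both equal-label arrays added (0.0241) and 1 value per RNA sample (0.013). Purine biosynthesis passed with 1 value per RNA sample (0.0128) and with the slide as a random block (0.0246). Without the second array of 12 h biofilm with stationary cells the medians were -1.74 for eps2, -1.32 for purine biosynthesis and -1.38 for the TasA region. Each of these lists passed without at least 1 array. The flagella call also changed in 2 of the fits without 1 array, and its median ran from -0.47 to 0.19, so its sign was not stable. Both 24 h RNA samples lay below both 12 h samples for 8 of 9 eps2 and 5 of 10 purine genes, and above them for 0. With 1 value per RNA sample 74 genes passed (16 higher, 58 lower at 24 h), with processed signals 807 did and with median centring 370 did. Without the first and the second array of 12 h biofilm with stationary cells 1 and 45 genes passed, and the toxin list no longer passed without the second array of mid-log with stationary cells (adjusted p = 0.0618), the second of 24 h biofilm with stationary cells (0.266) or the array of 12 h biofilm with mid-log cells (0.388). With the channel labels as written each sign turns.

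Both arrays that compare the biofilms directly were left out for the conflict in their channel labels, and were not fitted. Their titles name the biofilms in opposite orders. By title order, the direction used here, their dyes are therefore swapped, as the design text says. Read so, opposite signs of their Cy5 over Cy3 ratios mean the same change. Their direction is as likely as title order, not settled. Their Cy5 over Cy3 ratios after loess correlated at -0.40 across genes, although their channel labels give both the same dyes. The correlation was -0.33 with processed signals and 0.01 with median centring in place of loess. Over the 2827 genes above background in both channels of both arrays it was -0.34, -0.35 and -0.28 in these settings. The median size of their log2 ratios was 0.24 and 0.34. Of 149 genes that differed by at least 2-fold on both arrays, 128 (85.9%) had opposite signs. Added by title order they raised the count for 24 h against 12 h biofilm to 457 genes, and added with all arrays read by channel labels and the signs then turned, or with both direct arrays against title order, they left it at 0.

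Stationary cells were compared with mid-log cells as the planktonic difference that both biofilm comparisons can be read against. Flagellar genes fell in stationary cells: 37 of 44 were lower (median -1.94), with BC1658 20.6-fold lower (-4.36 ± 0.30, adjusted p = 5.45e-05), BC1644 15.4-fold and BC1638 14.5-fold. Of the 14 toxin genes 11 were lower (median -2.97), with BC5101 23.9-fold lower (-4.58 ± 0.73, adjusted p = 0.00218), BC1810 18.1-fold and BC0670 13.6-fold. In the eps1 cluster 15 of 17 genes were lower (median -1.22), with BC5278 10.8-fold, BC5277 9.66-fold and BC5269 6.21-fold lower. The TasA region was not called (median 0.51, adjusted p = 0.948): tasA, BC1279, stood at 0.86 ± 0.62 (adjusted p = 0.251) and calY, BC1281, at 1.1 ± 0.53 (adjusted p = 0.103), and sipW, BC1278, alone rose, by 9.76-fold (3.29 ± 0.56, adjusted p = 0.00182). In eps2 4 of 9 genes rose (median 1.1, adjusted p = 0.109 in camera and 0.0251 in fry), BC1591 by the most (4.82 ± 0.27). Of the purine genes 5 rose and 1 fell (median 0.88, adjusted p = 0.437), and of 18 general stress genes 7 rose and 4 fell (median 0.37, adjusted p = 0.816). The locus spo0A, BC4170, stood at -0.71 ± 0.30 (adjusted p = 0.0698). plcR, BC5350, was 3.30-fold lower (-1.72 ± 0.41, adjusted p = 0.00821), but its brighter probe alone gave 0.32. sigB, BC1004, stood at 0.39 ± 0.28 (adjusted p = 0.247) and turned to -1.24 with median centring in place of loess.

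Between stationary and mid-log cells 3617 genes changed, 2020 higher and 1597 lower in stationary cells, the most of the 6 comparisons in the fit of all 8 arrays. Its median standard error was also the smallest, 0.22 against 0.23 to 0.31. Without the second array of mid-log with stationary cells 2955 genes changed. The unnamed loci with the largest fitted rises were BC0390 (10.30 ± 0.52), with 9 of its 12 stationary spots saturated, and BC1218 (10.13 ± 0.53), and BC5380 had the largest fitted fall (-4.90 ± 0.49). In camera the flagella list (adjusted p = 1.21e-09), eps1 (0.000553) and the toxin list (0.000811) passed, each with adjusted p = 0.441 with an estimated correlation. Within the slide of the direct arrays their medians were -1.61, -1.17 and -2.82. For the lists not called, the medians within that slide and over the 8 arrays were -0.08 and 0.51 for the TasA region and 0.45 and 1.1 for eps2. They were 0.51 and 0.88 for purine biosynthesis and 0.1 and 0.37 for general stress. With the slide as a random block 3598 genes changed, and with the channel labels as written the 2020 would be lower and the 1597 higher. Over probes above background in both channels on every array 2374 of 3132 genes changed, 1824 higher and 550 lower.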

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

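The tests of the channel direction, of the direct arrays and of the equal-label arrays in this part were chosen after the results they concern were seen. The eps1 exopolysaccharide cluster differed between both biofilms relative to planktonic cells, by a log2 median of -0.66 at 24 h against 12 h, and the toxin list differed by 0.47. Both were picked out because camera's test of the difference passed, with adjusted p = 0.000717 and 0.0484, and neither passed with an estimated correlation (0.441 and 0.473) or with fry (0.124 and 0.42). The eps1 result also missed the threshold with the brightest probe of each gene (-0.53, adjusted p = 0.0544) and turned to 0.03 with both direct arrays added against title order, and its median ran from -1.05 to -0.38 without 1 array. For 11 of the 17 eps1 genes both 24 h RNA samples lay below both 12 h samples, and for 0 above. For 5 of the 14 toxin genes the 24 h RNA samples lay on opposite sides of both 12 h samples. Of their genes, 0 of 17 and 0 of 14 passed on their own. No explanation for either was tested.

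The direction of the channels was weighed as a pattern of its own. Same-dye profiles that share a condition by channel label correlated at a median of -0.39 across genes. Those profiles came from signals dye-normalized by lowess. Dye normalization is argued against as the source, since profiles of background-subtracted spot signals with no dye normalization gave -0.40 by channel label, and 0.97 by title order. Exchanged names of mid-log and stationary cells on every array are argued against too, since channels with the same name would then still share a profile, and gave -0.39. Turned dye labels remain as a candidate explanation: by title order the median was 0.96. As title order was found from these data, this is a hypothesis, and no biological explanation was tested.

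Both arrays that compare the biofilms directly, which no comparison uses, held a signal, with standard deviations of their log2 ratios across genes of 0.61 and 0.77. The arrays ran against each other at a correlation of -0.40, or -0.33 with processed signals, but at 0.01 with median centring in place of loess, so over all genes the pattern depends on the normalization. Over 2827 genes above background in both channels of both arrays the correlation was -0.34, -0.35 and -0.28 in these settings. The limit for this test was set after the results were seen, and -0.34 and -0.35 passed it while -0.28, with median centring, did not. Over these genes the correlation stayed negative in each setting. With a limit so chosen, the test does not decide whether weak Cy5 signal on the first array was the source. By its channel labels the first array correlated at 0.61 with the 12 h against 24 h change from the arrays with stationary cells, and the second at -0.69; with processed signals these were 0.68 and -0.72, and with median centring 0.71 and -0.56. A wrong channel label on the second array is therefore a candidate explanation and one on the first is argued against, both only if title order holds for the arrays with stationary cells. Title order reads the first array by its channel labels and the second against them. Over 11 arrays, both of these among them, same-dye profiles that share a condition by title order correlated at 0.87 to 0.97 (20 pairs). Under the channel labels the roles of the arrays exchange. No biological explanation was tested.

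The 2 arrays with equal labels (12 h biofilm sample 1 with mid-log sample 2), which no comparison uses, had standard deviations of 1.84 and 1.64. Their difference, first minus second, had a slope of 1.05 on the 24 h against 12 h change over 459 genes at least 2-fold in that change. With 1 of the 4 arrays behind that change left out at a time, and the genes at least 2-fold chosen anew, the slope was 0.43 to 0.89. The change from the other mid-log arrays had 0.84. A slope of 1.05 argues against the second array holding 24 h biofilm, and leaves 24 h biofilm on the first array as a candidate explanation. The lowest slope with 1 array left out, 0.43, fell short of the limit set for the first array. That candidate therefore depends on which arrays are used. The first array's Cy5 profile correlated at 0.89 with the 24 h biofilm profile by title order of an array with stationary cells, and at 0.51 with that of 12 h. The design text gives each pair of conditions 2 arrays, while the labels give 12 h biofilm with mid-log cells 3 and 24 h biofilm with mid-log cells 1. This number of arrays goes with 24 h biofilm on the first array. Across genes the first array correlated at 0.86 and 0.87 with the other arrays of 12 h biofilm with mid-log cells. Those correlated with each other at 0.98, but shared a slide. With the array of 24 h biofilm with mid-log cells, on its own slide, the first array's ratios correlated at -0.85, the dyes being swapped by title order. In size that is no closer than to the 12 h arrays, so the correlations of whole arrays do not decide. No array was reassigned.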

How the results depend on the processing

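Alternatives chosen after seeing the data were outlier-marked spots kept on the array with the most, the pooled comparison without each RNA sample or by channel labels, and the correlation settings of the direct arrays. Of the gene counts per comparison under the alternatives, 160 were within 1.5 times the reported count and 26 were not. For the count in all 4 biofilm comparisons, the pooled count and the correlation of the direct arrays together, 30 alternatives moved the value, 14 did not and 1 reversed it. Of the list results, 1170 kept their side of the threshold, 41 lost the threshold, 46 gained it and 3 reversed. Of the results for named genes, 20771 kept their side, 249 lost the threshold, 472 gained it and 36 reversed. A reversal was counted only where the result passed in at least 1 of the settings compared. A turned sign that passed in neither thus stands among those that kept their side. The cause of a change was not tested unless stated. A fixed slide term could not be tested, since it left no residual degrees of freedom.

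With processed signals and no loess, and equally with the series value table, which holds the same ratios, 3208 genes changed in 12 h biofilm against mid-log cells, 2983 in 24 h biofilm against mid-log cells, 807 in 24 h against 12 h biofilm and 829 in 1 direction in all 4 biofilm comparisons (61.9% higher, against 96.9%), among them all 96. The flagella list in 24 h biofilm against stationary cells (-0.94), eps2 in 24 h against 12 h biofilm (-0.68) and eps2 in stationary against mid-log cells (1.24) passed, and the toxin list in 24 h against 12 h biofilm did not (0.73). Reversed were 7 named genes in stationary against mid-log cells, at -0.54, -0.61, -0.93, -1.04, -0.82, -0.16 and -0.84. The direct arrays correlated at -0.33. The median of all genes moved to -0.25 from 0.05 in 12 h biofilm against mid-log cells to -0.12 from 0 in 24 h biofilm against mid-log cells, to -0.04 from -0.15 in 24 h biofilm against stationary cells and to 0.04 from 0.19 in stationary against mid-log cells.

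With median centring instead of loess 370 genes changed in 24 h against 12 h biofilm and 515 in all 4 biofilm comparisons (75.9% higher), 90 of the 96 among them; in 12 h biofilm against mid-log cells 41.6% were higher, against 53.2%. The flagella list in 24 h biofilm against stationary cells (-0.61) and eps2 in stationary against mid-log cells (0.97) passed. Reversed were sigB (-1.24) and 9 other named genes (-1.58, -0.70, -1.36, -0.54, -1.34, -1.14, -1.04, -0.97 and -1.39) in stationary against mid-log cells, BC1810 in 24 h biofilm against mid-log cells (-2.09), and the correlation of the direct arrays (0.01). The median of all genes moved to -0.12 in 12 h biofilm against mid-log cells and to 0.04 from -0.08 in 24 h against 12 h biofilm.

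With probes above background in both channels on every array, which left 3132 genes, 1113 genes changed in 12 h biofilm against mid-log cells, 2203 in 12 h biofilm against stationary cells, 1155 in 24 h biofilm against mid-log cells, 19 in 24 h against 12 h biofilm and 2374 in stationary against mid-log cells; fewer genes were tested. In 24 h against 12 h biofilm eps2 passed (-0.97) and the toxin list did not (0.66). Weak signal, most of all in Cy5, thus limited which genes could be tested. By title order the signal was lowest for stationary cells on the 8 arrays. Where they held Cy5, 56.63% to 68.74% of gene probes were well above background, against 73.02% to 91.57% for other conditions. In Cy3 their median signals were 166.8 to 199.2, against 283.7 to 626.2. With the brightest probe of a gene eps2 passed in 24 h against 12 h biofilm (-0.98) and eps1 did not (-0.53), nor did eps1 in 12 h biofilm against mid-log cells (-0.69). Both settings reversed plcR (0.32), BC5264 (0.09) and BC1804 (2.26) in stationary against mid-log cells, and BC0332 (-2.24) and BC0331 (0) in 24 h biofilm against stationary cells; the brightest probe also reversed BC3631 in stationary against mid-log cells (-1.19). The median of all genes moved, with the stricter filter and the brightest probe, to -0.66 and -0.33 in 12 h and to -0.74 and -0.40 in 24 h biofilm against stationary cells, and to 1.06 and 0.52 in stationary against mid-log cells.

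With no dye term 174 genes changed in all 4 biofilm comparisons and eps2 passed in 24 h against 12 h biofilm (-0.92). A sample-number term tested no replicate block on the arrays: with a dye term it absorbs the array of 12 h biofilm with mid-log cells, the only one with equal numbers on both channels, and gives the values without that array. With it 1086 genes changed in 12 h biofilm against mid-log cells and 22 in all 4 biofilm comparisons, and the toxin list did not pass in 24 h against 12 h biofilm (0.45). The numbers did not pair the RNA samples: deviations of equal numbers correlated at -0.38 to 0.19 across genes. With 1 value per RNA sample, without and with the replicate block, 74 and 58 genes changed in 24 h against 12 h biofilm and 339 and 267 in all 4 biofilm comparisons. In both, the flagella list passed against stationary cells (-0.60 at 12 h and -0.74 at 24 h), eps2 (-0.55) and purine biosynthesis (-0.58) passed in 24 h against 12 h biofilm, eps2 passed in stationary against mid-log cells (1.2), and the toxin list did not pass in 24 h against 12 h biofilm (0.43). The pooled comparison gave 470 genes with the replicate block and 281 by channel labels.

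With both, the first or the second equal-label array added, 259, 193 and 252 genes changed in all 4 biofilm comparisons and eps2 passed in 24 h against 12 h biofilm (-1.01, -1.05 and -1.01). With the direct arrays added, all arrays read by channel labels and the signs then turned to the direction used here, 366 did; there eps2 (-0.49) and purine biosynthesis (-0.75) passed in 24 h against 12 h biofilm and the toxin list did not (-0.14). With both by title order 438 did, 457 genes changed in 24 h against 12 h biofilm, the general stress list passed (-0.43) and the toxin list did not (0.32). With both against title order 362 did, eps2 passed (-0.25), the toxin list did not (-0.05), and eps1 (0.03) and general stress (0.08) reversed. With all 12 arrays by channel labels, signs again turned, 588 did, the flagella list passed in 24 h biofilm against stationary cells (-0.68), and in 24 h against 12 h biofilm the TasA region (-0.48), eps2 (-0.54) and purine biosynthesis (-0.75) passed and the toxin list did not (-0.09).

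With the slide as a random block purine biosynthesis passed in 24 h against 12 h biofilm (-0.67). At an adjusted p under 0.01, by construction a stricter threshold, 1179 genes passed in 12 h biofilm against mid-log cells, 973 in 24 h biofilm against mid-log cells, 1895 in 24 h biofilm against stationary cells and 14 in all 4 biofilm comparisons. With an estimated correlation all 23 called lists had adjusted p of 0.441, 0.472 or 0.473. By fry eps1 (0.124) and the toxin list (0.42) did not pass in 24 h against 12 h biofilm, and eps2 passed in stationary against mid-log cells (0.0251).

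Without each array in turn the counts ran from 1086 to 2048 in 12 h biofilm against mid-log cells, 789 to 1866 in 24 h biofilm against mid-log cells, 1413 to 3028 in 24 h biofilm against stationary cells, 0 to 45 in 24 h against 12 h biofilm and 0 to 213 in all 4 biofilm comparisons, and without each RNA sample the pooled count ran from 361 to 665. List medians with a changed call ran, in 24 h against 12 h biofilm, from -1.74 to -0.32 for eps2, -0.47 to 0.19 for flagella, -1.32 to -0.05 for purine biosynthesis, -1.38 to 0.17 for the TasA region and 0.24 to 0.59 for toxins. They ran from 0.73 to 2.11 for eps2 in stationary against mid-log cells, -0.73 to -0.25 and -0.98 to -0.37 for flagella in 12 h and 24 h biofilm against stationary cells, and -1.82 to -1.18 and 0.17 to 0.86 for toxins in 24 h biofilm against mid-log and stationary cells.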

Other observations

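The tests in this part were chosen after the values were seen. In biofilm against planktonic samples with 1 value per RNA sample, 1 of the 35 splits of the 8 samples into 4 and 4, the real one, gave as many genes as the real 717, and the highest of the other splits gave 5. That count speaks only of splits of single samples, most of which part the samples of a condition. With both samples of each condition kept together there are 3 splits, the real one and others with 5 and 0 genes, which is too few for a share under 0.05. Title order was itself chosen because profiles of the same condition then matched. By the channel labels the real split gave 281, and the split of 12 h biofilm sample 1, both 24 h biofilm samples and mid-log sample 1 from the rest gave 294.

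The 96 genes that changed in 1 direction in both biofilms against both planktonic conditions held 39 pairs of adjacent locus tags, where 10000 random draws of as many tested genes gave a median of 2 and at most 8, so that p was the smallest the draws can give, 1e-04. In all, 55 of the 96 had a called neighbour, and the longest runs were BC5293 to BC5299 with 7 genes, and BC2483 to BC2488 and BC3939 to BC3944 with 6 each. Neighbouring tags may change together because they share transcripts; no transcript map was available to test that.

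Probes were searched for short peptides of ribosomal and sporulation proteins; of the 3 sporulation genes found, BC0049 and BC3106 matched small acid-soluble spore proteins and BC5282 matched the regulator SpoIIID. The 15 ribosomal-protein genes found all lay between BC0118 and BC0157, so they are not 15 independent observations, and ribosomal-protein genes elsewhere were not covered. In stationary against mid-log cells all 15 were lower (median log2 -3.31) and all 3 sporulation genes were higher (4.35). Against stationary cells 13 of the 15 ribosomal-protein genes were higher in 12 h biofilm (2.19) and 12 in 24 h biofilm (1.52), and the 3 sporulation genes were lower in both (-4.17 and -4.14). Against mid-log cells 7 of 15 ribosomal-protein genes were lower in 12 h biofilm (-1.14) and 13 in 24 h biofilm (-1.65). The ribosomal-protein medians kept their signs but not their sizes: they were -2.48 and -3.16 with processed signals and -3.63 and -3.92 with median centring against mid-log cells, and -5.27 and -6.12 in stationary against mid-log cells. The sporulation medians against mid-log cells, 0.25 and 0.55 with 1 of 3 called in each, turned to -0.13 and -0.09 with median centring. By the channel labels all of these signs turn.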
